A study of Mus musculus with 21 samples.

How the data were processed

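The series holds 21 samples of mouse fibro-adipogenic progenitors (FAPs) of 2 genotypes, called WT and Prdm16 per the labels. Analysed here were 5 RNA libraries (3 WT, 2 Prdm16), 6 libraries of H3K9me2 domains (3 of each genotype) and 2 libraries of LaminB1 domains (1 of each). The 8 input samples were not used here. Per the labels, RNA libraries were made from polyadenylated RNA by SMART-seq2. The submitters' processing notes name Bowtie 1.2.2, STAR 2.7, featureCounts and DESeq2 1.20, and the builds mm10, dm6 and GRCm38. The role of each program and build and the caller of the domains are not given in the sources used here.

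The deposited count table held whole numbers, raw counts for 55341 genes in 5 libraries. The deposited normalized table held a signal per gene and library that the authors made by dividing the counts by 1 size factor per library. DESeq2 size factors computed here gave the same values to within 0.0005. The deposited comparison table held the mean normalized signal, the log2 fold change of Prdm16 over WT and its standard error on the log2 scale, each from the authors' own comparison. It also held the authors' p-value for 32193 genes and adjusted p-value for 6237, with limits of 0.5 on the log2 fold change and 0.1 on p per the file headers and names. The calls follow the adjusted p, with 0.0995 the largest among them. The authors' method of adjustment is not given in the sources used here. Their log2 fold changes were shrunken: with the grouping that matched their p, values shrunken by apeglm 1.24.0 lay within 0.02 of theirs for all 10781 genes compared, and the median ratio to unshrunken values was 0.42. Each deposited domain list held a chromosome, a start, an end and the authors' score, whose making is not given in the sources used here. Domains did not overlap within a library. Their boundaries were multiples of 3 kb for H3K9me2 and of 4 kb for LaminB1, so bins of 1 kb held them exactly.

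Library totals were 10657791, 7053114 and 10284864 counts for the libraries labelled WT replicates 1, 2 and 3, and 8448654 and 5839587 for those labelled Prdm16 replicates 1 and 2. Read depth of the domain libraries is unknown, so no interval was given for them.

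Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes passed edgeR's expression filter at its defaults (15240 genes), libraries were scaled by trimmed mean of M-values, and genotype was tested two-sided by robust quasi-likelihood with Benjamini-Hochberg adjustment and a threshold of 0.05. The labels do not pair the replicate numbers, so no block was used. Of the tested genes, 13785 (90.5%) were located in the RefSeq annotation of GRCm38.p6. CPM values refer to the scaled library size. Gene lists fixed before the data were examined covered lineage, matrix, signalling, chromatin and metabolic groups and markers of other cell types. Lists with at least 3 tested members (27 lists) were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 27 lists. The sex-linked, other leukocyte and erythroid lists had fewer tested members and were not tested. Fry tests whether a list's genes move one way on balance and compares the list with no other genes.

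Named genes followed a rule fixed before the data were examined. It takes Prdm16, then up to 12 higher and 12 lower genes among those called. The remainder is filled by smallest unadjusted p among genes with a mean of at least 5 CPM in a genotype and all Prdm16 libraries on one side of all WT libraries. Symbols made of Gm and digits, Rik symbols, unnamed IDs and pseudogenes were excluded from naming. No gene was called, so all 24 places were filled by unadjusted p. Up to 4 members per list by smallest p, and Myod1, Myog, Pdgfra, Pparg, Ehmt1, Ehmt2 and Lmnb1, were named as well. Myf5 belonged to that set but did not pass the expression filter. The rule for regions takes the 5 longest lost and gained H3K9me2 regions and the 3 longest LaminB1 regions of each genotype alone.

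Domains were compared in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and drawn with matplotlib 3.10.9. Lost regions were covered in all 3 WT libraries and no Prdm16 library, gained regions the reverse, and kept regions in all 6 libraries. Single values of 3 against 3 libraries were compared by exact two-sided permutation, whose smallest p is 0.1, and similarity by an exact one-sided permutation over 10 splits. Genes belonged to a domain class when a share of at least 0.5 of the gene body lay in it. Classes were tested with camera and fry as the lists were. Family and list shares in domains were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment.

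The coverage of X and the reduction of LaminB1 to equal covered length were examined after seeing the data.

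The authors' p-values were compared with DESeq2 1.42.0 run on each of the 10 groupings of the 5 RNA libraries into 3 and 2. A p within 1% of the authors' counted as matching, over genes with a mean above 50. This check, the comparison with apeglm and the alternatives built on the check were chosen after seeing the data.

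Alternatives tried for RNA were DESeq2 size factors, upper-quartile and total-count scaling, no filter and a stricter filter, DESeq2's Wald test, limma-voom, a replicate block, each library left out, genes on X and Y or of the mitochondrial genome left out, and the authors' limits. Added after seeing the data were the exchange of the libraries labelled WT replicate 3 and Prdm16 replicate 1, the fit without both, and equal covered length for H3K9me2. Alternatives for domains were the upper 0.5 of domains by score, autosomes alone, gaps under 50 kb merged, each library left out, at least 2 of 3 libraries against none, bins of 10 kb, regions of at least 50 kb, and other LaminB1 sets.

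The RNA procedures were tested on simulated data with the means, depths and spread of the 5 RNA libraries. Over 14893 genes, edgeR recovered 7.46% of 67 genes changed 2-fold, 79.1% of 67 changed 4-fold and 97.0% of 66 changed 8-fold, with 8.27% of the calls false. With no gene changed, 0 of 14848 genes were called. Camera called the planted list and 0 of 20 unchanged lists. The simulated genes varied independently, so this cannot show how often camera calls unchanged lists whose genes vary together. On made-up domains the domain code found 8 of 8 planted lost and 6 of 6 planted gained regions. Planted regions were identical in all libraries of a group, so this checks the code and not its sensitivity.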

Results

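Fibro-adipogenic progenitors (FAPs) are mesenchymal cells of skeletal muscle that expand after injury and can become fat or fibrous tissue. The series compared FAPs of mice with floxed Prdm16 alleles and a tamoxifen-inducible Cre at Pdgfra (called Prdm16) with FAPs of floxed mice lacking the Cre (called WT). Mice received tamoxifen for 5 days, rested for 7 days and were injured with cardiotoxin, and FAPs sorted 5 days later were grown for 4 to 5 days. RNA was sequenced in 3 WT and 2 Prdm16 libraries, with 10657791, 7053114 and 10284864 counts in the WT libraries and 8448654 and 5839587 in the Prdm16 libraries. Domains of H3K9me2, a histone mark of repressed chromatin, were given for 3 libraries of each genotype. Domains of LaminB1, a protein of the nuclear lamina, were given for 1 library of each genotype, so LaminB1 had no replicates. The labels do not say whether replicates came from separate animals, so the p-values measure the spread between these samples.

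Prdm16, the targeted gene and a zinc-finger regulator known for directing brown fat identity, was measured to check the labels. It lies on chromosome 4 from 154316122 to 154637360 (GRCm38). It had 171, 94 and 59 counts in the libraries labelled WT replicates 1, 2 and 3, and 91 and 86 counts in those labelled Prdm16 replicates 1 and 2. Its level was 11.8 ± 5.66 CPM (SD, n = 3) in WT and 12.9 ± 3.29 CPM (SD, n = 2) in Prdm16. The log2 fold change was 0.13 with an SE of 0.47 (edgeR's quasi-likelihood test, two-sided, Benjamini-Hochberg adjusted p = 0.9996), so the count did not separate the genotypes. The sign turned to -0.21 without WT replicate 3 and to -0.14 without Prdm16 replicate 2. The count can include transcript outside the floxed part and cannot by itself test the deletion.

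The authors' comparison table did not match the labels of the count table. With the libraries labelled WT replicate 3 and Prdm16 replicate 2 taken as the Prdm16 pair, DESeq2 gave a p within 1% of the authors' p for 10781 of 10781 genes. With the pair as labelled, 123 genes (1.14%) matched. The library labelled Prdm16 replicate 2 also differed from the rest in sex-linked genes. It held 15 counts of Xist, the RNA that coats the inactive X chromosome, against 3483 to 4652 in the others, and it held transcripts of 4 Y genes. Libraries are therefore named by their labels throughout, and every RNA direction follows these labels unless the authors' table is named.

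**Figure D1:**
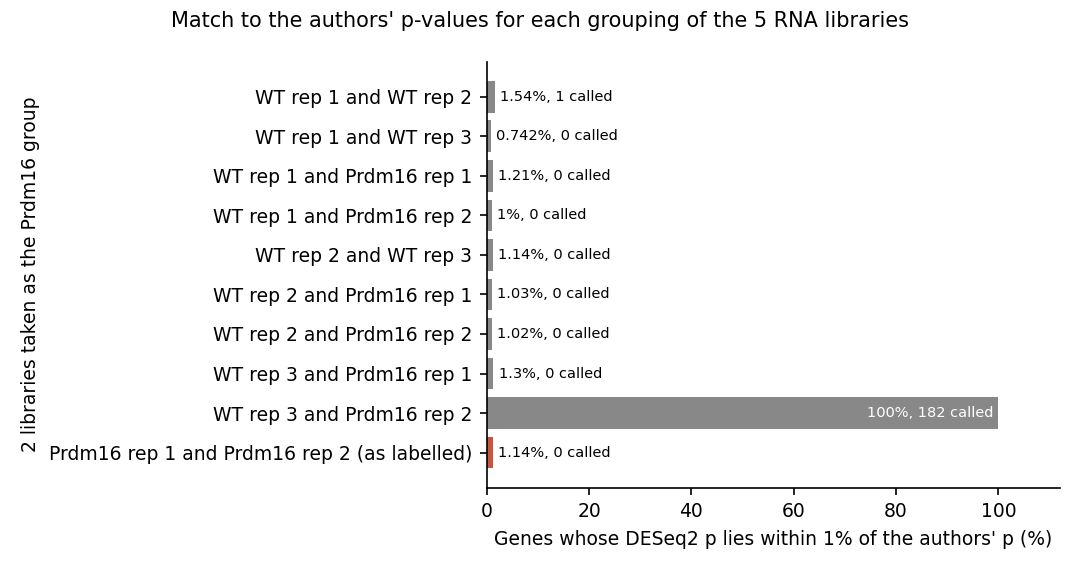
Bars show, for each choice of 2 of the 5 RNA libraries as the Prdm16 group (vertical axis), the percentage of genes whose DESeq2 p lies within 1% of the authors' p (horizontal axis), with the genes called by edgeR written beside each bar. The pair of labelled WT replicate 3 and Prdm16 replicate 2 reached 100% with 182 genes called, and the pair as labelled 1.14% with 0 called.

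The RNA comparison asked which genes differ between the genotypes. By the labels, the gene nearest to a call was Ndufs5, a subunit of respiratory complex I on chromosome 4 from 123712710 to 123718186. It had 43.3, 36 and 35.6 CPM in the libraries labelled WT and 5.49 and 5.33 CPM in those labelled Prdm16, a log2 fold change of -2.82 with an SE of 0.27 (edgeR, adjusted p = 0.085). Sod1, the cytosolic superoxide dismutase, had 497 ± 133 CPM (SD, n = 3) against 259 ± 48.8 CPM (SD, n = 2), a log2 fold change of -0.94. Among genes with higher values, Thbs4, a matrix protein of tendon and muscle (chromosome 13, 92751586 to 92794818), had 34.0 ± 3.76 CPM (SD, n = 3) against 95.7 ± 41.7 CPM (SD, n = 2). Spp1, the secreted phosphoprotein osteopontin (chromosome 5, 104435111 to 104441053), had 7192 ± 1361 CPM (SD, n = 3) against 13011 ± 2749 CPM (SD, n = 2).

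None of these genes passed the test. By edgeR, 0 of 15240 genes had an adjusted p under 0.05, and 378 had an unadjusted p under 0.05 (169 higher, 209 lower) where chance gives 762. In the libraries labelled Prdm16, 1345 genes lay above all WT libraries and 1365 below, together 17.8% where chance gives 20%. The other 11 lower genes named by the rule had log2 fold changes from -1.57 to -0.56. They included the respiratory subunit Cox7a2 (-0.56), the ribosomal proteins Rpl39 (-0.56) and Rpl37a (-0.58), the histone gene Hist1h4d (-0.65), Cenpx (-0.61), Cavin3 (-0.67), Nhsl2 (-0.82), Ap4s1 (-1.03), Rp9 (-1.23), and Irak1bp1 (-1.57). Rpl39, Rpl37a and Hist1h4d have near-identical copies, which makes their counts uncertain. The other 10 higher genes were Casq1 (2.09) and Casq2 (1.51), which store calcium in muscle, Bex1 (1.35), Cd80 (1.15), a ligand of T cells, Pmaip1 (0.87), which promotes apoptosis, Chic1 (0.76), Stom (0.73), Csgalnact1 (0.71), Dusp6 (0.68), which restrains ERK, and Slc39a14 (0.67), a zinc transporter. All of them had an edgeR adjusted p of 0.9996.

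Other tools called few genes by the labels. DESeq2's Wald test called 1 gene, Ndufs5 (adjusted p = 4.4e-13), with 432 genes at an unadjusted p under 0.05, and limma-voom called 0, with 323. Without a filter on low counts edgeR called 25 genes (10 higher, 15 lower), among them Ndufs5 (4.1e-11), Thbs4 (2.4e-04), Spp1 (0.0020), Casq2 (0.0069) and Sod1 (0.021). Without the library labelled Prdm16 replicate 1 it called 4 genes, Xist, Ddx3y, Eif2s3y and Uty, all sex-linked and named after their values were seen. Without the libraries labelled WT replicate 3 and Prdm16 replicate 1 it called 93 genes (14 higher, 79 lower), and with these 2 exchanged 182 (24 higher, 158 lower), both chosen after seeing the data.

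Genes of the muscle contractile apparatus were higher as a group in the libraries labelled Prdm16. By the labels all 33 tested sarcomere genes had positive log2 fold changes, with a median of 1.00 (camera adjusted p = 1.8e-19). With an estimated correlation the call was lost (adjusted p = 0.978 with an estimated correlation), and fry gave an adjusted p of 0.755. With the 2 doubtful libraries exchanged the median was 0.56 and camera kept its call (adjusted p = 3.0e-06, and adjusted p = 0.643 with an estimated correlation), with Myoz2 at -0.17. At the preset correlation camera also called the list in groupings that mix the labels. The adjusted p was 1.3e-26 with WT replicates 1 and 2 as the pair and 4.7e-12 with WT replicate 3 and Prdm16 replicate 1. The list was also called with WT replicates 1 and 3 (0.0012) and with WT replicate 1 and Prdm16 replicate 2 (0.034) as the pair. Some groupings were not called, such as WT replicate 2 with Prdm16 replicate 2 (0.986). The camera call therefore does not set the labelled pair apart. Of the 33 genes, 19 lay above all WT libraries, 14 had an unadjusted p under 0.05, and 0 were called over all genes tested, while 1, Casq2, was called adjusted over the list alone. Casq2 had 12.3 ± 3.53 CPM (SD, n = 3) against 35.0 ± 0.81 CPM (SD, n = 2), and Myh3, the embryonic myosin heavy chain, had 54.9 ± 26.9 CPM (SD, n = 3) against 135 ± 29.8 CPM (SD, n = 2). Actn2, which anchors actin at the Z disc, had a log2 fold change of 1.18. The library labelled WT replicate 3 stood apart within its group, with a median of 3.75 log2 CPM over the sarcomere genes against 2.93 and 2.80 in the other WT libraries and 4.30 and 4.20 in the Prdm16 libraries. Des, the muscle intermediate filament and a marker of myoblasts, had 27.2, 31.6 and 108 CPM of the library total in WT replicates 1 to 3 and 81.4 and 89.7 in the Prdm16 libraries. Des is also a marker of pericytes. Of the other myoblast markers Myod1, Itga7, Cdh15 and Megf10 were likewise higher in WT replicate 3 and both Prdm16 libraries than in WT replicates 1 and 2, while Sdc4 and Vcam1 were not. Myod1 was highest in WT replicate 3 (30.6 CPM of the library total, against 12.8 and 15.4 in the Prdm16 libraries), and the list of these markers was not called (4 of 7 higher, camera adjusted p = 0.540).

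Neuronal genes were the other group with members all in one direction. All 10 tested members were higher in the libraries labelled Prdm16 with a median of 0.48 (camera adjusted p = 0.0071, fry adjusted p = 0.0048). The adjusted p was 0.978 with an estimated correlation. The glutamate receptor genes Grik2 (1.11) and Gria1 (1.35), the adhesion gene Ntm (1.21) and the vesicle fusion gene Snap25 (0.72) had the smallest p, and 0 members were called adjusted over the list alone or had an unadjusted p under 0.05. Ntm and Snap25 were measured at low counts. Ntm had 0.48, 1.72 and 0.75 CPM in WT and 1.63 and 2.84 in Prdm16, and Snap25 1.15, 0.86 and 1.49 against 1.63 and 2.31. With the 2 doubtful libraries exchanged the camera call was lost (adjusted p = 0.746).

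Tendon and cartilage genes were higher in part. Of 8 tenocyte markers 6 were higher, with a median of 1.07 (camera adjusted p = 0.021, and adjusted p = 0.980 with an estimated correlation). Adjusted over the list alone 5 were called, Thbs4 (1.49), Fmod (1.80), Comp (1.60), Mkx (0.89), a tendon transcription factor, and Col11a1 (0.74), and 0 over all genes tested. Thbs4, Mkx and Col11a1 were higher in both Prdm16 libraries than in every WT library. Fmod and Comp rose mainly in Prdm16 replicate 2. Fmod had 1.17 to 1.97 CPM of the library total in WT against 2.01 and 8.9 in Prdm16 replicates 1 and 2. Comp had 2.81 to 7.94 against 7.46 and 20.4. Scx (-1.07), the tendon lineage regulator, and Egr1 (-0.53) had lower values. Of 12 chondro-osteogenic genes 9 were higher, with a median of 0.44 (camera adjusted p = 0.020, and adjusted p = 0.978 with an estimated correlation). Cilp (1.84), Comp, Col2a1 (0.79) and Sox5 (0.64) led it by p, and 0 were called adjusted over the list alone. The tenocyte call was lost without WT replicate 2 (adjusted p = 0.109), without WT replicate 3 (0.178) or without Prdm16 replicate 2 (0.306), and the chondro-osteogenic call without WT replicate 3 (0.111) or Prdm16 replicate 2 (0.306). Exchanging the 2 doubtful libraries ended both calls (0.485 and 0.673).

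Nuclear genes of mitochondrial respiration were lower in part in the libraries labelled Prdm16. Of 27 members 18 were lower and 10 lay below all WT libraries, with a median of -0.08 (camera adjusted p = 0.042, and adjusted p = 0.980 with an estimated correlation). The cytochrome oxidase subunits Cox6c (-0.56), Cox7b (-0.48) and Cox5b (-0.49) and Ndufa4 (-0.60) had the smallest p, 5 members had an unadjusted p under 0.05, and 0 were called adjusted over the list alone. The call was lost without WT replicate 2 (adjusted p = 0.142), WT replicate 3 (0.217) or Prdm16 replicate 2 (0.605) and with the 2 doubtful libraries exchanged (0.592). It was also lost with a replicate block (0.267) and, in further fits chosen after seeing the data, with upper-quartile scaling (0.060), without genes on X and Y (0.087) and with no filter on low counts (0.159). The 10 tested genes of the mitochondrial genome were not called (adjusted p = 0.972), with 5 higher and 5 lower and a positive median (0.02) and mean (0.06) where camera gave a downward direction.

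Across the 27 lists camera thus called 5 (4 higher, 1 lower), none with an estimated correlation. In the other groupings of the 5 RNA libraries camera called 2 to 11 lists, so a count of 5 does not set the labelled pair apart. It called 10 without WT replicate 1, 10 without Prdm16 replicate 1, 10 with the 2 doubtful libraries exchanged and 11 without them. Myogenic regulators had 12 of 18 members higher and a median of 0.36 (camera adjusted p = 0.142). The master regulators Myod1 and Myog had log2 fold changes of -0.02 and 0.52 and Mef2c 0.49. Satellite cell and myoblast markers had a median of 0.27 (0.540). White adipogenic genes split 12 to 12 (0.463), with median and mean of -0.0031 and -0.10 where camera gave an upward direction, and Pparg, the adipogenic master regulator, at -0.02. Brown and beige fat genes had 9 of 12 members lower and a median of -0.24 (0.381). FAP identity genes had a median of -0.07, a mean of 0.01 and an upward camera direction (0.861), with the FAP receptor Pdgfra at -0.15 and Cd34 at 0.51. Fibrosis and extracellular matrix genes had 27 of 40 members higher and a median of 0.24 (0.142), and glycolysis and hypoxia genes 17 of 24 higher and a median of 0.11 (0.972).

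Cell cycle genes had 27 of 34 members lower and a median of -0.13 (camera adjusted p = 0.152), with the replication clamp Pcna at -0.59. Arrest and senescence genes had a median of -0.09 (0.942), interferon genes -0.37 with 29 of 34 lower (0.202), and inflammatory genes 0.12 (0.280). H3K9 methylation and heterochromatin genes had a median of 0.08 (0.835), with the H3K9me2 methyltransferase pair Ehmt1 and Ehmt2 at -0.24 and 0.25. Nuclear lamina genes had a median of -0.09 (0.835), with Lmnb1 at -0.72. The Prdm family had a median of -0.07 against a mean of 0.0039 and an upward direction (0.972), and germline and silenced loci -0.21 (0.463). Unfolded protein response genes had a median of 0.17 (0.463) and immediate early genes -0.07 (0.771). Of the markers of other cells, macrophage genes had a median of 0.18 (0.463), endothelial -0.19 (0.972, with fry upward), pericyte and smooth muscle 0.10 with a mean of -0.14 (0.787), and Schwann -0.17 with an upward camera direction (0.942).

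**Figure D2:**
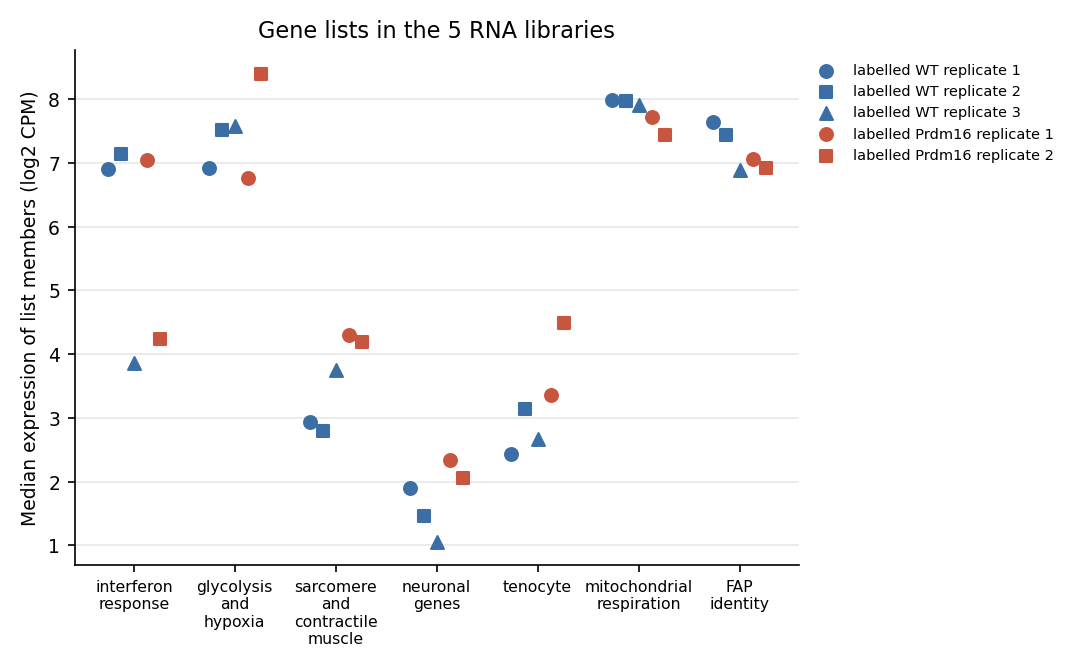
Points show the median expression of each gene list (horizontal axis) in each of the 5 RNA libraries, in log2 CPM (vertical axis), coloured by labelled genotype and shaped by replicate. Interferon genes sit at 3.86 and 4.23 in labelled WT replicate 3 and Prdm16 replicate 2 and at 6.90 to 7.13 in the other libraries, and sarcomere genes sit lowest in WT replicates 1 and 2.

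In the authors' table, whose grouping differs from the labels as given above, interferon genes and hypoxia genes stood out. The authors called 471 genes (123 up, 348 down). Their log2 fold changes were shrunken values, smaller in size than the unshrunken ones for 99.96% of genes. Counts here take the list members to which the authors gave an adjusted p. Of 34 interferon genes 32 were down (Fisher's exact test, one-sided, adjusted p = 5.3e-37), with authors' log2 fold changes of -4.79 for Ifit3, -4.56 for Isg15 and -4.43 for Ifit1. Ifit3 had 478 and 759 CPM in the libraries labelled WT replicates 1 and 2 and 564 in Prdm16 replicate 1, against 21.8 in WT replicate 3 and 21.4 in Prdm16 replicate 2. Of 23 glycolysis and hypoxia genes 13 were up (adjusted p = 9.4e-16), among them Car9 (2.29), Egln3 (1.5), Pdk1 (1.40) and Ldha (0.94). Of 31 fibrosis and matrix genes 7 were up (adjusted p = 3.1e-05), such as Timp1 (0.85), and 6 down (adjusted p = 0.050), such as Eln (-2.72) and Col6a1 (-1.04). Of 20 FAP identity genes 5 were down (adjusted p = 0.050), Pi16 (-1.88), Hic1 (-1.17), Tcf7l2 (-0.80), Ly6a (-0.78) and Pdgfra (-0.54), and Myod1 was up (1.05). Over all 15240 genes tested here, in a test added after seeing the data, the same calls were 7 up (adjusted p = 4.8e-07) and 6 down (0.0029) of 40 matrix genes, 13 up of 24 hypoxia genes (1.8e-20) and 5 down of 28 FAP identity genes (0.0035). In that test 5 of 25 inflammatory genes were also down (0.0029), and 2 of 7 myoblast markers, Myod1 and Megf10, up (0.010). Of the authors' calls 470 were tested here by the labels, 0 were called by edgeR and 3 had an unadjusted p under 0.05. With the 2 libraries exchanged, 181 of the 182 edgeR calls were also calls of the authors, in the same direction.

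The H3K9me2 comparison asked whether the place of this mark differs between the genotypes. H3K9me2 domains covered 1017, 635 and 887 Mb in the WT libraries and 575, 841 and 690 Mb in the Prdm16 libraries. The means were 846 ± 194 Mb (SD, n = 3) and 702 ± 134 Mb (SD, n = 3), a difference of -145 Mb (exact permutation test, two-sided, p = 0.4). Domain numbers were 1045 ± 146 (SD, n = 3) and 1012 ± 90.7 (SD, n = 3, exact p = 0.8), and mean lengths 820 ± 211 kb (SD, n = 3) and 701 ± 166 kb (SD, n = 3, exact p = 0.4). With 3 libraries against 3 the smallest p is 0.1. The libraries of both genotypes overlapped in each of these measures.

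**Figure D3:**
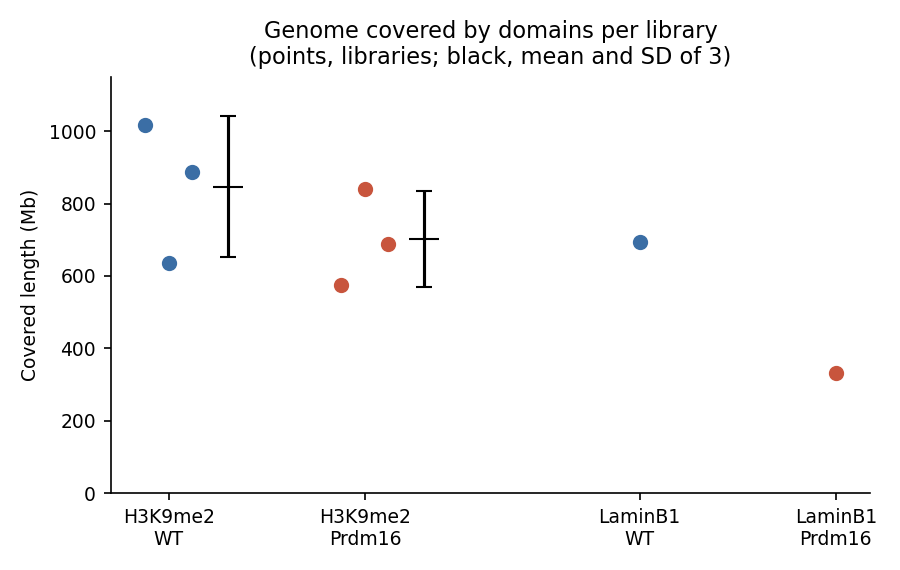
Points show the genome length covered by domains in each library (vertical axis, Mb) by mark and genotype (horizontal axis), with the mean and SD of the 3 H3K9me2 libraries of each genotype in black. WT and Prdm16 libraries overlap for H3K9me2, and the single LaminB1 libraries stand at 693 and 331 Mb.

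Libraries of one genotype were not shown to share H3K9me2 domains more than libraries of different genotypes. The Jaccard index of covered bases averaged 0.576 within and 0.561 between genotypes, a difference of 0.0147 (exact one-sided permutation, p = 0.6). The most similar libraries were WT replicates 1 and 3 (0.788) and the least similar WT replicate 3 and Prdm16 replicate 1 (0.446). The difference changed sign on autosomes alone (-0.0011) and without WT replicate 1 (-0.038) or WT replicate 3 (-0.039).

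**Figure D4:**
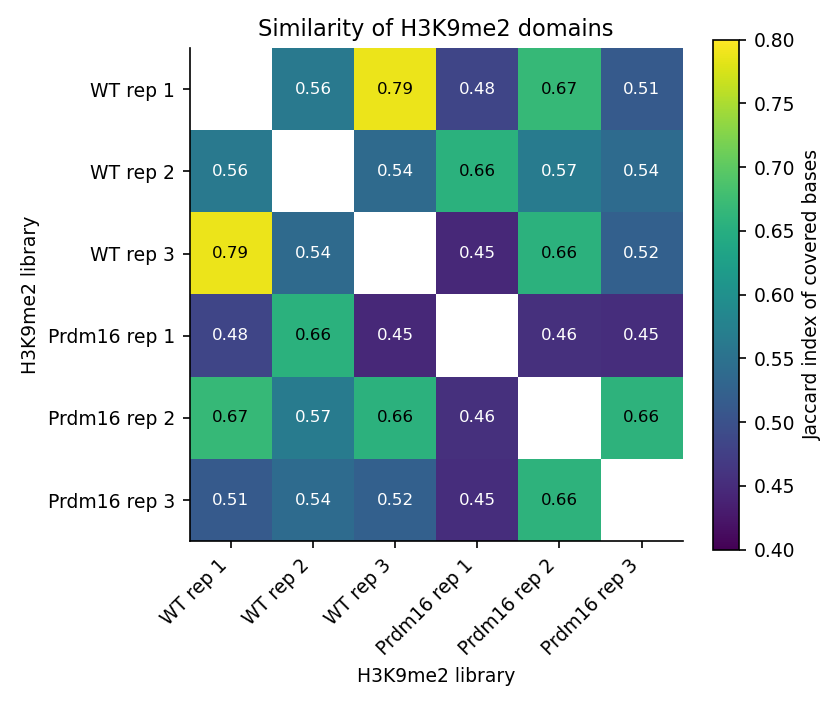
Squares give the Jaccard index of bases covered by H3K9me2 for each pair of the 6 libraries (both axes), with colours drawn from 0.4 to 0.8 and no unit. Prdm16 replicate 1 is closest to WT replicate 2 (0.66) and not to a library of its own genotype.

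Regions with H3K9me2 in all 6 libraries covered 300.9 Mb in 602 regions. Lost regions, covered in all WT and no Prdm16 library, made up 10.6 Mb in 110 regions with a median of 28.5 kb, and 6.78 Mb of them lay on X. The 5 longest were all on X, at 45585001 to 46629000 (Actrt1), 65736001 to 66258000 (no protein-coding gene), 41775001 to 42294000, 115317001 to 115794000 (no protein-coding gene) and 99975001 to 100425000. The third of them holds Thoc2, of the mRNA export machinery, Xiap, an inhibitor of apoptosis, and Stag2, of cohesin, and the fifth Eda, a ligand of skin appendage development, and Awat2. Gained regions made up 6.31 Mb in 76 regions with a median of 24 kb, and 0 Mb of them lay on X. The longest were on chromosome 18 from 8724001 to 9207000 (no protein-coding gene), 14 from 29073001 to 29448000 (Cacna2d3, a calcium channel subunit), 5 from 141246001 to 141606000 (Sdk1, an adhesion molecule of synapses), 2 from 136533001 to 136872000 (Ankef1 and Snap25) and 3 from 21465001 to 21792000 (no protein-coding gene). Leaving out a library relaxes the rule for both lengths, so they can only stay or rise. A rise alone therefore does not show that a length depends on that library. The lost length was 91.0 Mb without WT replicate 2, 44.7 Mb without Prdm16 replicate 1 and 34.9 Mb without Prdm16 replicate 2. The gained length was 10.8 Mb without WT replicate 1, 15.5 Mb without WT replicate 2, 38.4 Mb without Prdm16 replicate 1 and 9.58 Mb without Prdm16 replicate 2.

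The X chromosome was looked at on its own after much of the lost length was seen to lie there. X held 63.8% of the lost length over all libraries. Its share was 38.4% without WT replicate 2, 38.5% without Prdm16 replicate 2 and 53.2% to 64.2% without any other library. On X, H3K9me2 covered 78.4%, 42.8% and 65.4% in the WT libraries and 43.6%, 23.9% and 7.48% in the Prdm16 libraries. The means were 62.2 ± 18.1% (SD, n = 3) and 25 ± 18.1% (SD, n = 3), a difference of -37.2 (exact permutation, two-sided, p = 0.2). Autosomes differed by -3.30 percentage points (exact p = 0.6). Relative to autosomes, X was covered 2.19, 1.87 and 2.07 times as much in WT, and 2.15, 0.73 and 0.27 times in Prdm16 replicates 1, 2 and 3, a difference of -0.99 (exact p = 0.3).

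**Figure D5:**
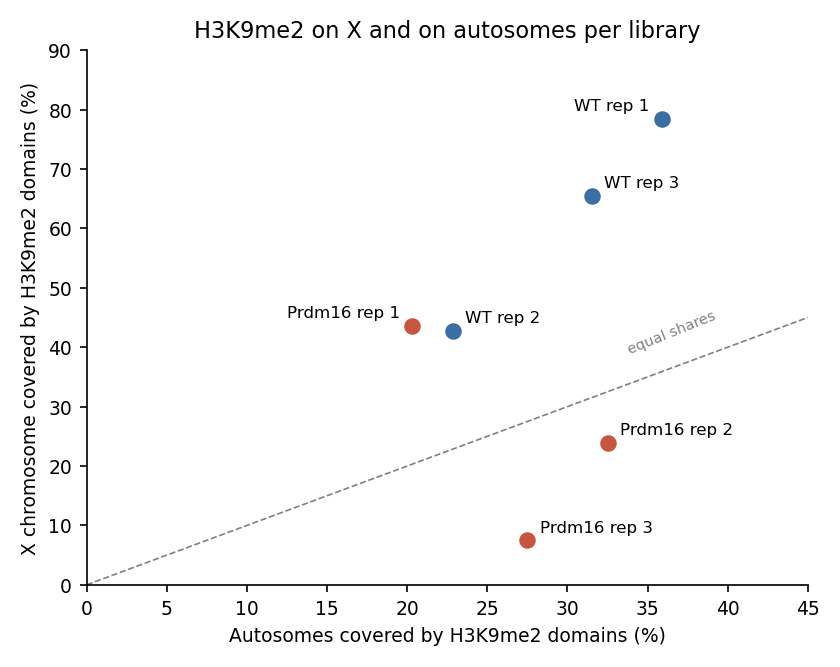
Each point is 1 H3K9me2 library, placed by the percentage of autosomes (horizontal axis) and of X (vertical axis) covered by domains, with a dashed line of equal shares. Prdm16 replicates 2 and 3 lie below the line at 23.9% and 7.48% of X, and the other 4 libraries lie above it.

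LaminB1 domains, which mark chromatin at the nuclear lamina, covered 693 Mb in 1066 domains in the WT library and 331 Mb in 986 domains in the Prdm16 library. They shared 322.5 Mb, so 97.5% of the Prdm16 domains lay within WT domains and 46.5% of the WT domains within Prdm16 domains (Jaccard index 0.460). With the WT domains reduced to the highest-scoring 329.8 Mb, both libraries shared 200.2 Mb (Jaccard index 0.435). The longest regions of WT alone were on chromosome 14 from 111728001 to 114432000 (no protein-coding gene), chromosome 2 from 85272001 to 87448000, where 99 protein-coding genes are almost all olfactory receptors, and chromosome 2 from 98708001 to 100840000 (no protein-coding gene). Regions of Prdm16 alone made up 8.10 Mb, the longest on X from 22484001 to 22724000, chromosome 15 from 31652001 to 31852000 and chromosome 19 from 54136001 to 54336000, with no protein-coding gene. With 1 library per genotype the difference has no replicate check, and the covered length moves with how much was called.

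The share of H3K9me2 inside LaminB1 domains of the same genotype was 48.6%, 43.4% and 48.8% in the WT libraries and 22.2%, 12.2% and 12.5% in the Prdm16 libraries. The means were 46.9 ± 3.09% (SD, n = 3) and 15.6 ± 5.66% (SD, n = 3), a difference of -31.3 (exact permutation, two-sided, p = 0.1, the smallest p possible). All 3 libraries of a genotype were set against 1 LaminB1 library, and the Prdm16 LaminB1 domains covered less of the genome. H3K9me2 libraries of either genotype had 34.6% to 48.8% in WT LaminB1 and 12.2% to 22.2% in Prdm16 LaminB1. The p of 0.1 was therefore fixed by the LaminB1 library used and does not test the H3K9me2 libraries. Against the WT LaminB1 domains for all libraries the difference was -6.82 (exact p = 0.2), and against shared LaminB1 domains -2.80 (exact p = 0.4).

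Kept H3K9me2 regions and LaminB1 regions of WT alone held fewer genes per Mb than the genome, and few of the genes in kept H3K9me2 and LaminB1 domains reached 1 CPM. The genome had 8.04 protein-coding genes per Mb, kept H3K9me2 regions 2.21, lost regions 4.80, gained regions 1.11, shared LaminB1 regions 6.24 and LaminB1 regions of WT alone 3.47. In the libraries labelled WT, 8.76% of 639 genes in kept H3K9me2 reached 1 CPM, as did 1.91% of 1889 in shared LaminB1 domains, 7.13% of 1248 in LaminB1 domains of WT alone and 65.6% of 17686 outside H3K9me2. Lost regions held expressed genes of X, such as Mpp1 (212 CPM), Thoc2 (150 CPM) and Stag2 (92.6 CPM), and 29.8% of their 47 genes reached 1 CPM, beside 3 of 5 genes in gained regions. Actc1, the cardiac actin, was an expressed gene in kept H3K9me2 (69.9 CPM).

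The expression of genes in these domains was then compared between genotypes by the labels. Genes in kept H3K9me2 were higher, 59 of 91 with a median of 0.22 (camera adjusted p = 0.024, and adjusted p = 0.173 with an estimated correlation; fry adjusted p = 0.092), with the glutamate receptor Grm7 (1.62), the cation exchanger Slc24a3 (1.59) and the perinatal myosin Myh8 (1.35) first by p. Of the 91, 0 were called over all genes or over the class alone and 1 had an unadjusted p under 0.05. The class shares members with lists described above, such as Myh8 with the sarcomere list and Ntm with the neuronal list. Of 38 sarcomere genes 5 and of 30 neuronal genes 11 lay in kept H3K9me2, tested or not, so these results overlap. The call was lost without WT replicate 2 (adjusted p = 0.170), WT replicate 3 (0.098), Prdm16 replicate 1 (0.271) or Prdm16 replicate 2 (0.227) or with the whole gene body required inside (0.098), and the median was -0.12 with the 2 doubtful libraries exchanged (0.746). Other classes were not called: 15 genes in lost H3K9me2 had a median of -0.03 (camera adjusted p = 0.398), 7 in gained H3K9me2 0.44 (0.155), 138 in LaminB1 of WT alone -0.07 (0.521, with fry upward), 68 in shared LaminB1 -0.09 (0.178) and 11 in LaminB1 of Prdm16 alone -0.01 with a mean of 0.25 and an upward direction (0.155). Without WT replicate 1, gained H3K9me2 (0.036) and shared LaminB1 (0.035) were called as well. With the whole gene body required inside, LaminB1 of Prdm16 alone was the class called (5 genes, median 0.21, adjusted p = 0.027).

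Muscle and fat genes were placed against these domains. Of all 21900 protein-coding genes, 18113 lay in no H3K9me2 library. Of 22 myogenic regulators, Eya1 and Msc were covered by H3K9me2 in all 6 libraries, Peg3 in WT replicate 1 alone and the other 19, Myod1, Myog and Myf5 among them, in none. The share in kept regions was 9.09% against 3.0% of all protein-coding genes (Fisher's exact test, two-sided, adjusted p = 1 over the lists). Pax7, the satellite cell regulator, and Peg3 lay in LaminB1 domains of WT and not of Prdm16, with 94.3% and 100% of the gene. Of all 21900 protein-coding genes, 1277 lay in LaminB1 domains of WT alone and 36 in those of Prdm16 alone. With 1 LaminB1 library per genotype, these placements have no replicate check. Of 31 white adipogenic genes 0 were covered in any H3K9me2 library. Of 25 brown and beige fat genes 4 were covered in at least 1 library, with Ppargc1a, the coactivator of mitochondrial biogenesis, in all 6.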

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

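The tests of explanations for the 3 patterns weighed here, and every bound, were chosen after the results were seen. The comparisons of H3K9me2 with other splits were planned before the data were examined.

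The library labelled Prdm16 replicate 2 held counts of 4 Y-linked genes, 372 of Ddx3y, 436 of Eif2s3y, 181 of Kdm5d and 333 of Uty, where the other 4 RNA libraries held 0 to 2. These genes stood out because they lie outside the comparison and exceed the limit that a count of 0 allows.

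The authors' table called 471 genes, of which the fit by labels called 0. The groups as labelled with another program version or setting do not account for it, since 0.638% of the authors' calls had an unadjusted p under 0.05 by labels. An exchange of the libraries labelled WT replicate 3 and Prdm16 replicate 1 may account for it: 100% of the DESeq2 p-values matched in that grouping, and the highest match in any other of the 10 groupings was 1.54%. Whether the headers of the count table or the grouping in the authors' comparison is wrong stays open. With the 2 libraries exchanged, Prdm16 had a log2 fold change of -0.41 and was not called (edgeR adjusted p = 0.82), so these possibilities cannot be told apart.

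Sarcomere genes had a median log2 fold change of 1.00 in the libraries labelled Prdm16. Carry-over of myoblasts may contribute, and 7 satellite cell and myoblast markers had a median of 0.27 with 4 of 7 higher, too few and too mixed to decide. Des, Itga7, Cdh15, Megf10 and Myod1 were higher in WT replicate 3 and both Prdm16 libraries than in WT replicates 1 and 2, as the sarcomere medians were (Itga7 at 35.0, 26.5 and 24.3 against 14.2 and 15.6 CPM), while Sdc4 and Vcam1, the most abundant of these markers, were not (log2 fold changes -0.17 and -0.43), FAPs express Vcam1 too, and Myod1 was highest in WT replicate 3 (30.6 CPM). Of the 10 groupings, 2 gave a sarcomere median as large in size, with -1.33 as the most extreme other value (WT replicates 1 and 2 as a pair), and 10 groupings cannot give a share under 0.05. An effect of genotype stays open and untested beyond the comparison itself.

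H3K9me2 on X was low in Prdm16 replicates 2 and 3, at 0.73 and 0.27 times the autosome share. A shorter covered length of these libraries is argued against, since the lower of their autosome percentages was 27.5 against 22.8 to 35.9 in WT. Sex of the animals could underlie it, and the test had nothing to read, since domains covered 0 Mb of Y in all 6 libraries. Genotype in every library also stays open: Prdm16 replicate 1 had a ratio of 2.15, within the WT range, and 1 library excludes nothing. Inputs were not used here and the RNA came from other libraries, so sex and genotype cannot be told apart.

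The difference in H3K9me2 similarity, within minus between genotypes, was 0.0147, and 6 of 10 splits gave a value as large, the highest other being 0.0993. Each split has a longer and a shorter side, and these sides were matched after the data were seen. On the longer side 5 of 10 splits gave as much as the 10.6 Mb of lost length, the highest other being 89.9 Mb. On the shorter side 2 of 10 gave as much as the 6.31 Mb of gained length, the highest other being 7.04 Mb. With 10 splits a share under 0.05 is out of reach.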

How the results depend on the processing

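Alternatives with the 2 doubtful libraries exchanged or left out, equal covered length and the further camera fits named below were chosen after the data were seen. The other alternatives were fixed before. Of the alternative values, 74 for whole comparisons stayed on their side with their direction, 36 moved and 7 reversed. For named genes 501 stayed, 9 passed the threshold and 13 reversed. For called gene lists 32 stayed and 28 lost their call. For domain classes 50 stayed, 9 lost their call, 3 passed and 4 reversed. Except where stated, the cause was not tested. Alternatives that place genes by transcription start site were not run, since the annotation used here gives no strand. Where 1 Prdm16 RNA library is left, it is assumed to vary like the others. In simulated data 7.46% of 2-fold changes were recovered at the spread estimated by the labels and 83.6% at 1 in 4 of that dispersion. Of the calls, 8.27% and 13.1% were false. The estimated spread would include differences from a wrong grouping, so the simulation cannot tell whether spread or grouping limited the calls. Depth was not varied.

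The count of 0 called genes moved to 1 with upper-quartile scaling, total counts, DESeq2's Wald test or the authors' limits (Ndufs5 in each), and to 25 with no filter, 182 with the 2 libraries exchanged and 93 without them. Leaving out each library gave 0 to 4. Prdm16 had a log2 fold change of -0.41 with the 2 exchanged and -0.21 to 0.44 over the libraries left out. Myod1 reversed to 1.38 with the 2 exchanged, 1.21 without them and 0.32 by limma-voom, and ranged from -0.44 to 1.07 over the libraries left out. Pparg reversed to 0.0033 with upper-quartile scaling and 0.12 by limma-voom, with a range of -0.29 to 0.35. Pdgfra ranged from -0.39 to 0.060, and Ehmt2 reversed to -0.22 with the 2 exchanged.

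The count of 5 called lists moved to 0 with an estimated correlation, 1 by fry, 10 with the 2 exchanged (0 with an estimated correlation) and 11 without them, and ranged from 4 to 10 over the libraries left out. Fewer samples or other groups are part of these alternatives. Camera run on further fits, chosen after the data were seen, did not call mitochondrial respiration with upper-quartile scaling (adjusted p = 0.060) or without genes on X and Y (0.087), and with no filter called sarcomere genes and tenocyte markers alone.

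With a replicate block, 1 gene was called (Ttn, 2.38, adjusted p = 0.016, named after its value was seen), Prdm16 had -0.23 and Myod1 1.10, 7 lists were called, and 0 domain classes. The labels do not say whether the numbers pair the libraries. Deviations of same-number libraries correlated at -0.113, -0.326 and 0.085 across H3K9me2 bins and 0.209 and -0.202 across genes. Bins and genes are not independent replicates. The deviations of the 2 Prdm16 RNA libraries mirror each other by construction (WT replicate 1 gave 0.209 and -0.209), so these values cannot decide on pairing. In the replicate block the covered length differed by -145 Mb (exact sign-flip permutation, p = 0.75) and the share in LaminB1 by -31.3 (exact p = 0.25, the smallest p possible). The share in LaminB1 uses 1 LaminB1 library per genotype, so its p does not test the H3K9me2 libraries.

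H3K9me2 similarity was -0.0011 on autosomes and ranged from -0.039 to 0.059 over the libraries left out. Lost length was 3.85 Mb on autosomes, 97.1 Mb with at least 2 of 3 libraries against none, and 11.6 to 91.0 Mb over the libraries left out. Gained length was 3.97 Mb in the upper 0.5 of domains by score, 44.5 Mb with at least 2 of 3, and 7.13 to 38.4 Mb over the libraries left out. Leaving out a library or asking for at least 2 of 3 relaxes the rule, so lost and gained length could not fall under these settings. Equal covered length gave 0.0188, 7.38 and 5.18 Mb. LaminB1 shared length was 251 Mb in the upper 0.5 of domains by score, 324 Mb with merged domains, 299 Mb on autosomes and 200.2 Mb at equal length.

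The count of 1 called domain class was 0 with an estimated correlation, with the 2 exchanged and without them, and 0 to 3 over the libraries left out. With the whole gene body inside it stayed 1, with LaminB1 of Prdm16 alone called in place of kept H3K9me2. LaminB1 of WT alone ranged from -0.12 to -0.0024 over the libraries left out, and its reversal is one of camera's direction. Gained H3K9me2 had a median of -0.11 with the 2 exchanged and -0.050 without them.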

Other observations

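All tests in this part were chosen after the data were seen. The gene lists were fixed before. The gene families were not among these lists and were formed from the opening letters of gene symbols, with at least 50 protein-coding members each. Among the fixed lists, neuronal genes were most often found in H3K9me2 domains. Of 30 neuronal genes 28 were covered in at least 1 library and 11 in all 6, a share of 36.7% against 3.0% of all protein-coding genes (Fisher's exact test, two-sided, adjusted p = 1.6e-08 over the lists). One of them, Snap25, lay in a gained region. Of 38 sarcomere genes 5 were covered in all 6 libraries (13.2%, adjusted p = 0.079), and of the mitochondrial respiration, glycolysis, unfolded protein and cell cycle lists 0 were covered in any library.

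Clustered receptor families for odours and pheromones lay largely in the LaminB1 domains. Of 1110 olfactory receptor genes 42.9% lay in shared LaminB1 domains (Fisher's exact test, two-sided, adjusted p = 7.0e-211) and 37.1% in domains of WT alone (adjusted p = 1.8e-234). The vomeronasal receptors Vmn1r and Vmn2r had 72.7% and 69.4% of their genes in shared domains (adjusted p = 1.7e-121 and 6.3e-59), and the cytochrome P450 family Cyp 36.4% (adjusted p = 1.8e-12). Keratin-associated Krtap genes had 32.1% in domains of WT alone (adjusted p = 1.4e-08). Neighbouring members of a family share domains, so they are not independent, and 24 families were tested.

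The zinc finger gene Zfp984, in shared LaminB1 on chromosome 4 from 147753974 to 147812229 and named after its values were seen, was the only gene edgeR called when the libraries labelled WT replicates 1 and 2 formed the pair. It had 14.9 and 13.2 CPM in these libraries and 0.28, 0.47 and 0.18 CPM in the other RNA libraries. In the first principal component, with 43.9% of the variance, the libraries labelled WT replicate 3 (49.8) and Prdm16 replicate 2 (38.9) lay opposite WT replicates 1 (-51.0) and 2 (-28.0), with Prdm16 replicate 1 at -9.63.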
